A study of Mus musculus with 60 samples.

How the data were processed

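RNA was extracted from liver, subcutaneous fat and visceral fat of mice fed a control or a Western diet for 12 weeks, with or without NaKtide induced by 300 mg/kg doxycycline in the diet. Libraries were made with a stranded TruSeq mRNA kit and read in pairs of 50 bp. Each of the 12 groups of tissue, diet and treatment has 5 replicates, and the study's design speaks of 5 mice per group. The labels do not say whether the same mice gave all 3 tissues or whether equal replicate numbers mean the same mouse, so p-values measure spread between these samples.

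The authors deposited 3 tables of 60 columns each over 54232 gene IDs. Per the file headers the first holds raw counts per gene, and its values are whole numbers. The deposited normalized table holds a signal, the raw counts divided by 1 size factor per library, a ratio that was constant within each of the 60 libraries to a relative tolerance of 1e-06. Per the file headers the last table holds FPKM. All tests here use the raw counts; the normalized and FPKM tables were read only to check them against the counts. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0 and DESeq2 1.20.0 and the GRCm38 build. The counting program, the annotation and its release are not given in the sources used here. Of the gene IDs 54079 carry a symbol, 54165 are found in GENCODE M21, which supplied coordinates, and 17945 have no count in any library. Where a symbol has several IDs, the one with more counts was used.

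Every column matched a sample through its tissue, group letters and replicate number. Depth was 3.18 to 9.78 M counts per library with a median of 6.41 M, and 3.18 to 7.16 in liver, 3.49 to 9.78 in subcutaneous fat and 4.19 to 9.49 in visceral fat. Where a gene has 0 counts in a group, the fold is given as at least the value reached with 3 counts over the whole group, and for 1 to 3 counts as a ratio with its counting interval; both cover counting error only, not the spread between animals. Libraries were checked for duplicates, for Xist and Y-linked transcripts, for mitochondrial share and for transcripts of other cell types.

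Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group, quasi-likelihood F test, Benjamini-Hochberg adjusted p 0.05, no fold threshold). One model with 4 groups was fitted per tissue, and 1 model of the 40 fat libraries for contrasts between depots. The contrasts are diet without NaKtide, NaKtide on each diet, and their interaction in each tissue, then visceral against subcutaneous fat on control diet and the difference between depots in the diet effect and in the NaKtide effect on Western diet, 15 in all. Genes tested numbered 12991, 15226, 17235 and 17788 for liver, subcutaneous, visceral and both fats, with a biological coefficient of variation of 0.251, 0.346, 0.675 and 0.558. CPM are scaled by TMM, and a prior count of 2 was used for log2 CPM.

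For 45 gene lists fixed before the data were examined, limma 3.58.1 camera was run with an inter-gene correlation of 0.01 and with the correlation estimated per list, on lists with at least 3 tested members. Members past adjusted p 0.05 were counted over all genes and over the list alone. Named genes follow a rule fixed at the same time. For diet contrasts and NaKtide on Western diet it takes the 6 largest rises and 6 largest falls past adjusted p 0.05 with a mean of at least 5 CPM and all 5 libraries of one group above or below the 5 of the other, without predicted genes. It takes 3 and 3 for the other contrasts, where interactions and differences between depots need no separated groups. It adds, for each list, up to 2 rising and 2 falling called members with the smallest p, or the 2 members with the smallest p if none was called, and a fixed set with Src, Adipoq, Lep, Tnf and Il6 in fat NaKtide contrasts whatever their p. The text prints a selection of the genes so picked, made after their values were seen, and some genes are not reported here.

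Alternatives fixed before the data were examined were RLE scaling, no low-count filter, DESeq2 1.42.0, replicate number as a block, voom with quality weights, a fit of the 2 groups alone, each library left out in turn and, for lists, an estimated correlation and the rotation test fry. Those chosen after seeing the data were a fit without the 8 visceral libraries above 1000 CPM of tract and testis genes, tests without muscle-rich genes, a liver fit without control-diet libraries 2 and 4, the mitochondrial share as a liver covariate, and a fat fit without 3 libraries on the other depot's side of 10 CPM of mesothelial genes. Contrasts that share libraries were compared with 20 simulations of no effect and with 20 divisions of the shared libraries.

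The code was tested on simulated data with 200 changed genes, 100 at 2-fold and 100 at 4-fold, in every contrast except NaKtide on control diet and the depots on control diet. Those had 0 changed genes, so the share recovered was not tested there. For diet, edgeR recovered 68% and 95% of them in liver, 61% and 87% in subcutaneous fat and 6% and 66% in visceral fat, with 4.68%, 2.63% and 0% false calls. For NaKtide on Western diet in visceral fat it recovered 8% and 68% with 3.8% false calls, where DESeq2 had 33.1% false calls. Camera called the moved list and 0 of 50 unmoved lists in each of the comparisons simulated. The simulated genes varied independently of each other. These lists therefore cannot show how camera's preset correlation fares on genes that vary together. Nothing here separates doxycycline from NaKtide, and sequence differences or splicing were not analysed here.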

Results

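Liver, subcutaneous fat and visceral fat were profiled by RNA sequencing in mice kept for 12 weeks on a control chow with 11% fat or on a Western diet with 42% fat, with or without NaKtide. NaKtide is a peptide derived from the Na,K-ATPase, and its transgene is induced by doxycycline in the food. Each of the 12 groups holds 5 libraries, 60 in all, with 3.18 to 9.78 M counts per library. Counts scaled to library size (CPM) are group means ± SD with n = 5 libraries, and log2 fold changes are given ± standard error. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg correction over all genes tested. The first group named is compared with the second. A rule fixed before the data were examined picked the genes to name, and those printed here are a selection from them made after their values were seen. The transgene has no entry among the 54232 gene IDs and was not analysed here, so group labels could not be checked against it. The labels also leave open whether mice without NaKtide ate doxycycline, and every NaKtide effect below includes any effect of the drug.

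**Figure D1:**
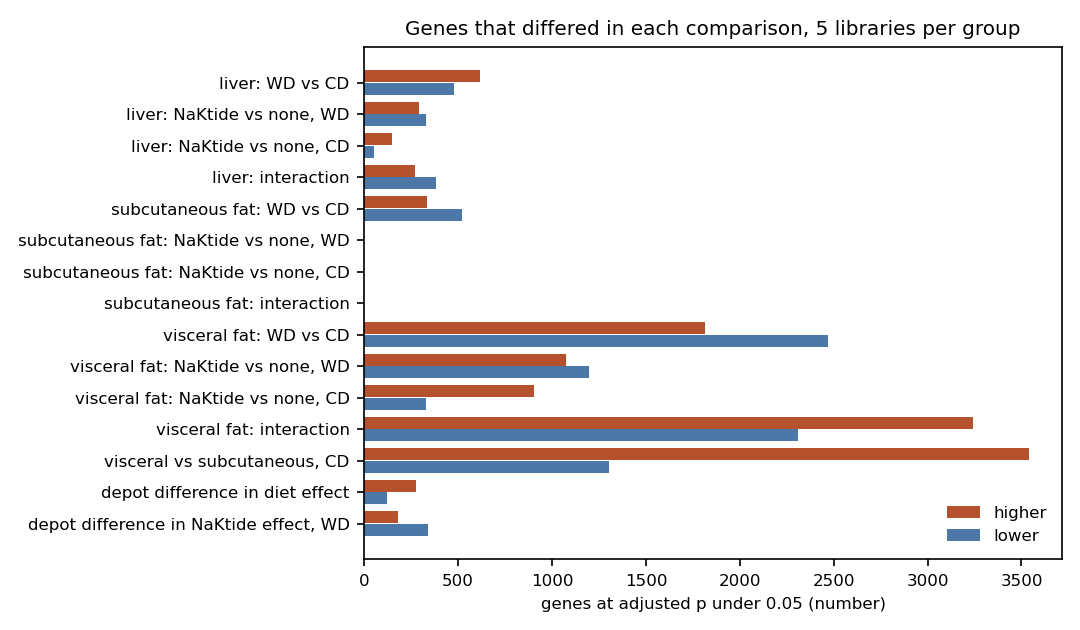
Number of genes called at adjusted p 0.05 in each of the 15 contrasts, with an upper bar for genes higher and a lower bar for genes lower in the first group. Liver and visceral fat changed with diet (1097 and 4287 genes) and with NaKtide on Western diet (622 and 2270), while subcutaneous fat changed with diet (854) and had 0 calls for NaKtide.

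Western diet turned the liver toward fat synthesis and storage. Pnpla3, a lipid droplet protein whose human form carries a common fatty liver variant (ENSMUSG00000041653, chromosome 15, 84167837 to 84187236, GRCm38), had 0 counts in the 5 control livers and 14.8 ± 9.58 CPM on Western diet, at least 121-fold higher with counting error (adjusted p = 0.0012). Its relative Pnpla5 rose by 7.13 ± 0.81 on the log2 scale (adjusted p = 9.6e-06). Elovl5, which elongates polyunsaturated fatty acids, rose by 2.28 ± 0.25 (adjusted p = 7.9e-06, 1000 ± 133 against 207 ± 61.1 CPM). Tkfc, the triokinase of fructose breakdown, rose by 1.73 ± 0.18 (adjusted p = 3.5e-06, 1250 ± 215 against 379 ± 62.7 CPM). Cidea, which fuses lipid droplets and is scarce in lean liver, went from 0.197 ± 0.193 to 43.3 ± 28.3 CPM (log2 7.76 ± 1.5, adjusted p = 0.0026). The fasting and stress hormone Fgf21 rose by 3.65 ± 0.76 (adjusted p = 0.0042). Rgs16, a G-protein regulator that follows carbohydrate supply in liver, rose by 4.71 ± 0.76 (adjusted p = 0.00047).

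Enzymes of oxidation and detoxification went the other way in these livers. Agxt, which clears glyoxylate in peroxisomes, fell by 2.21 ± 0.23 (adjusted p = 3.5e-06, 108 ± 22.5 against 498 ± 55.0 CPM). Eci2, an isomerase of peroxisomal and mitochondrial fat oxidation, fell by 1.12 ± 0.15 (adjusted p = 9.3e-05). Por, the electron donor of the microsomal P450 enzymes, fell by 1.26 ± 0.20 (adjusted p = 0.00037). Cyp2b10, the classic target of the receptor CAR, was lower by a ratio of counts of 68.6 (counting interval 23.1 to 336). Cd9, carried by lipid-associated macrophages, rose by 1.18 ± 0.20 (adjusted p = 0.001), Vim of mesenchymal cells by 1.41 ± 0.35 (adjusted p = 0.014) and Rrm2, which supplies deoxynucleotides for DNA synthesis, by 2.20 ± 0.30 (adjusted p = 9.3e-05). Acta1 of skeletal muscle fell by 5.17 ± 0.94 (adjusted p = 0.0014). Control-diet livers 2 and 4 hold muscle transcripts, as the 15 muscle genes sum to 351 and 697 CPM there.

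As gene groups, fatty acid synthesis rose in liver with 17 of 22 members called (18 when adjusted over the list alone, camera adjusted p = 3.58e-22, and adjusted p = 0.184 with an estimated correlation). The xenobiotic group fell with 7 of 19 (9 over the list alone, adjusted p = 7.44e-07, and adjusted p = 0.281 with an estimated correlation). Macrophage genes rose with 6 of 20 (10 over the list alone, adjusted p = 3.84e-06, 0.281 with an estimated correlation). Matrix genes rose with 5 of 22 (15 over the list alone, adjusted p = 4.52e-06, 0.332 with an estimated correlation). Other cell markers differed in sum as well, hepatocyte 52400 against 63100 CPM (exact p = 0.0159), cholangiocyte 49.5 against 20 and fibroblast progenitor 114 against 84.6 (exact p = 0.00794 each), all with adjusted p = 0.0662. Genes of fat oxidation fell with 3 of 25 (5 over the list alone, adjusted p = 6.41e-05, 0.422 with an estimated correlation). Over all 15 contrasts camera made 201 list calls with its preset correlation of 0.01, of which 0 held with an estimated correlation. In the whole transcriptome 1097 of 12991 genes were called, 617 higher and 480 lower, against 3031 at unadjusted p under 0.05. A fit of the 2 groups alone called 693, voom with quality weights 1744, and leaving out the muscle-containing livers, chosen after seeing the data, 656.

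NaKtide on Western diet left the liver with fewer transcripts of sterol synthesis and of several male-biased genes, and more macrophage transcripts. Mvd and Cyp51, enzymes of cholesterol synthesis, changed by -1.70 ± 0.27 (adjusted p = 0.0011) and -1.41 ± 0.26 (adjusted p = 0.0035). Hsd3b5, a steroid dehydrogenase made in male liver (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), fell by 6.70 ± 1.04 from 151 ± 81.3 to 1.19 ± 1.49 CPM (adjusted p = 0.0011). Elovl3, a male-biased fatty acid elongase, fell by 3.17 ± 0.38 (adjusted p = 0.00016, 24.0 ± 11.7 against 220 ± 62.7 CPM). Slco1a1, a male-biased organic anion carrier, fell by 3.57 ± 0.67 (adjusted p = 0.004). The female-biased Cyp2b13 rose by 4.24 ± 0.75 (adjusted p = 0.003, 12.9 ± 2.51 against 0.656 ± 0.65 CPM).

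Gpnmb and Trem2 mark lipid-laden macrophages. In the same livers Gpnmb rose by 3.25 ± 0.51 (adjusted p = 0.0011, 11.9 ± 3.24 against 1.23 ± 1.43 CPM) and Trem2 by 2.33 ± 0.43 (adjusted p = 0.004, 12.0 ± 4.8 against 2.36 ± 1.84 CPM). Por rose by 1.41 ± 0.20 (adjusted p = 0.00059), back to 386 ± 42.1 CPM from 146 ± 30.1. Gsta1, a glutathione transferase driven by Nrf2, rose by 2.65 ± 0.48 (adjusted p = 0.0035, 359 ± 106 against 57.1 ± 35.1 CPM). Cyba, the membrane subunit of NADPH oxidase, rose by 1.40 ± 0.29 (adjusted p = 0.008). Acot3, a peroxisomal thioesterase that PPAR alpha induces, rose by 4.15 ± 0.92 (adjusted p = 0.012).

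Liver cholesterol synthesis fell with 9 of 22 genes called (13 over the list alone, camera adjusted p = 7.35e-08, and adjusted p = 0.591 with an estimated correlation). The male-biased group fell with 8 of 13 (10 over the list alone, adjusted p = 1.18e-09, 0.233 with an estimated correlation), while its summed level was 11000 against 15000 CPM (exact p = 0.175, adjusted p = 0.337). Fatty acid synthesis fell with 3 of 22 (9 over the list alone, adjusted p = 0.000278, 0.607 with an estimated correlation), with a sum of 15700 against 20400 CPM (exact p = 0.159, adjusted p = 0.318). The female-biased group rose with 4 of 9 (4 over the list alone, adjusted p = 0.00574, 0.591 with an estimated correlation). Macrophage genes rose with 9 of 20 (15 over the list alone, adjusted p = 4e-12, 0.132 with an estimated correlation). Beside them, summed cholangiocyte markers were 141 against 49.5 CPM (exact p = 0.0317, adjusted p = 0.158) and Kupffer cell markers 339 against 471 CPM (exact p = 0.0714, adjusted p = 0.223). The oxidative stress group had 5 higher and 1 lower of 27 (9 and 1 over the list alone, adjusted p = 0.000396, 0.132 with an estimated correlation). Of 12991 genes 622 were called, 291 higher and 331 lower, against 3203 at unadjusted p under 0.05. RLE scaling turned the balance to 330 higher and 281 lower. Leaving out 1 library moved this count between 224 (without Western diet replicate 3) and 2281 (without NaKtide replicate 1), past 1.5 times for 9 of the 10 libraries. Exchanging Western diet replicate 1 and NaKtide replicate 1 gave 3904 calls, and whether their labels are exchanged was not tested. Their macrophage genes sum to 474 and 596 CPM, beside 198 to 329 in the other Western diet livers and 540 to 660 in the other NaKtide livers. Cholesterol synthesis (1493 and 1922 CPM, beside 1811 to 2222 and 1050 to 1477) lay nearer the opposite group in both. So did fatty acid synthesis (13800 and 23510, beside 19390 to 25120 and 12110 to 17840). Female-biased genes (284.7 and 974.2, beside 252.9 to 557.5 and 493.9 to 753.9) and Hsd3b5 (46.05 and 3.705 CPM) sided with the labels. DESeq2 called 1068, voom with quality weights 3904 and a fit of the 2 groups alone 321. The model with the mitochondrial share as covariate, chosen after seeing the data, called 152.

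On control diet NaKtide raised genes of lipid synthesis in liver. Fasn, which makes palmitate (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547), rose by 2.76 ± 0.40 (adjusted p = 0.0022, 1550 ± 768 against 229 ± 66.5 CPM). Bcl6, a repressor that favours the male liver programme, fell by 2.27 ± 0.36 (adjusted p = 0.0031), and the lipase Lpl fell by 2.12 ± 0.32 (adjusted p = 0.0022). Called members numbered 16 of 22 for cholesterol synthesis (20 over the list alone, camera adjusted p = 2.5e-24, 0.131 with an estimated correlation). They numbered 15 of 22 for fatty acid synthesis (21 over the list alone, adjusted p = 3.9e-21, 0.131 with an estimated correlation). Clock genes summed to 602 against 409 CPM (exact p = 0.00794, adjusted p = 0.0992), and a different hour of sampling was not tested. In total 201 genes were called in liver, 148 higher and 53 lower, against 2458 at unadjusted p under 0.05. Without single libraries the count ran from 59 (without NaKtide replicate 4) to 402 (without NaKtide replicate 2), past 1.5 times for 7 of the 10. DESeq2 called 433, a test with no low-count filter 308, the 2 groups alone 124, and leaving out the muscle-containing livers 83.

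**Figure D2:**
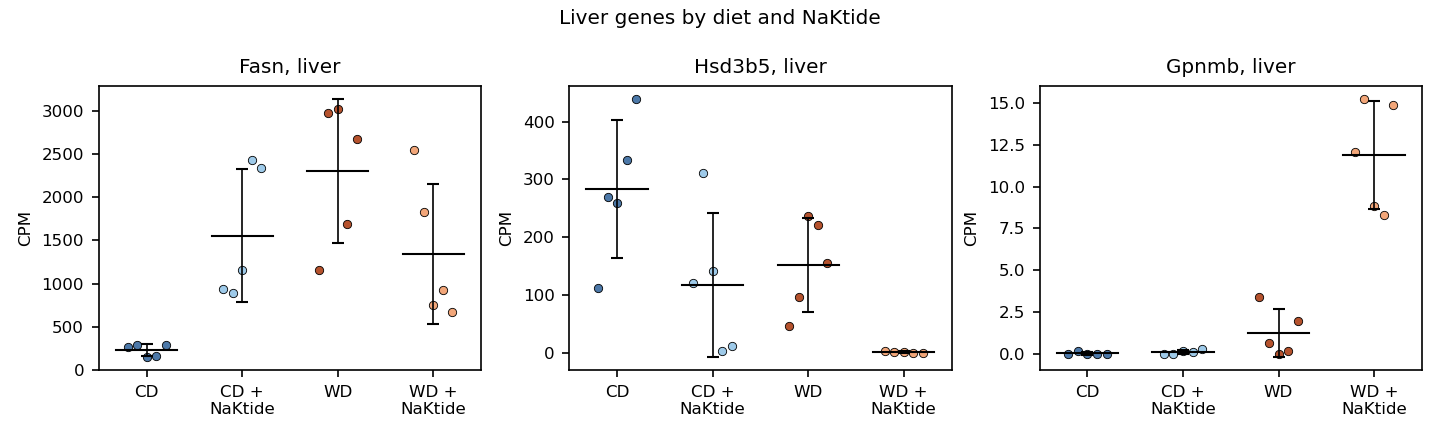
CPM of Fasn, Hsd3b5 and Gpnmb in liver, with 1 point per library, 4 groups of 5, and lines at the mean ± SD. Fasn is raised by NaKtide on control diet (1550 ± 768 CPM), Hsd3b5 is nearly lost with NaKtide on Western diet (1.19 ± 1.49 CPM) and Gpnmb is highest there (11.9 ± 3.24 CPM).

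The NaKtide effect on genes of lipid synthesis in liver differed between diets, tested as the interaction of diet and NaKtide. The NaKtide effect on Western diet minus that on control diet was -2.98 ± 0.37 for Mvd (adjusted p = 0.00033). It was -4.41 ± 0.65 for the citrate lyase Acly (adjusted p = 0.00083) and -3.43 ± 0.52 for the malic enzyme Me1 (adjusted p = 0.0011). For Lpl it was 3.27 ± 0.44 (adjusted p = 0.0004). The called share was 19 of 22 for cholesterol synthesis (21 over the list alone, camera adjusted p = 4.94e-21, 0.247 with an estimated correlation). It was 17 of 22 for fatty acid synthesis (19 over the list alone, adjusted p = 6.42e-16, 0.31 with an estimated correlation). Of 12991 genes 649 differed, 269 higher and 380 lower, against 3649 at unadjusted p under 0.05. RLE scaling gave 375 higher and 342 lower. Without single libraries the count ran from 192 (Western diet with NaKtide replicate 4) to 2738 (Western diet with NaKtide replicate 1), past 1.5 times for 18 of the 20. DESeq2 called 1559, voom with quality weights 3243, the mitochondrial covariate 168 and leaving out the muscle-containing livers 364.

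Of the genes that Western diet changed in liver, NaKtide moved 113 the opposite way on Western diet, 79 of them higher with diet and then lower and 34 lower and then higher, where independent lists would share 15.7 and 10.8. It moved 38 the same way, against 13.8 and 12.2. Both contrasts use the same Western diet libraries, so errors push their log2 changes apart. The correlation over all genes was r = -0.0981 (covariance -0.0331), where 20 simulations without any effect gave a median r of -0.478 (covariance -0.0428) and 0 opposite genes. Simulated genes varied independently of each other, whereas other splits of the same livers into groups gave up to 508 opposite genes. With the shared livers split between the contrasts in 20 ways the median r was 0.0368 (-0.238 to 0.344) and the median opposite count 27.5 (9 to 78). Leaving out Western diet replicate 3 lowered the count to 44 and leaving out NaKtide replicate 1 raised it to 251.

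Subcutaneous fat answered Western diet with sterol and fatty acid synthesis. Lss, which cyclizes squalene epoxide to lanosterol (ENSMUSG00000033105, chromosome 10, 76531588 to 76557138), rose by 2.32 ± 0.36 (adjusted p = 0.009, 120 ± 37.6 against 24.1 ± 8.8 CPM). The sterol dehydrogenase Nsdhl rose by 2.35 ± 0.39 (adjusted p = 0.0096). The desaturase Scd2 rose by 2.70 ± 0.44 (adjusted p = 0.0096, 1940 ± 276 against 298 ± 223 CPM). The acetyl-CoA synthetase Acss2 rose by 2.65 ± 0.47 (adjusted p = 0.0099) and the droplet coat Plin2 by 1.24 ± 0.25 (adjusted p = 0.013). Chemokines that call in monocytes and T cells also rose, Ccl2 by 3.29 ± 0.80 (adjusted p = 0.024) and Cxcl10 by 1.89 ± 0.39 (adjusted p = 0.013). The clock output genes Nr1d2 and Tef changed by -1.12 ± 0.20 (adjusted p = 0.01) and -1.55 ± 0.31 (adjusted p = 0.013). The alcohol-inducible Cyp2e1 fell by 2.75 ± 0.61 (adjusted p = 0.016).

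The largest falls in subcutaneous fat belong to skeletal muscle. Tcap, a sarcomere cap protein, fell by 10.63 ± 2.23 (adjusted p = 0.013, 0.567 ± 0.915 against 917 ± 646 CPM) and Eno3, the muscle enolase, fell by 7.54 ± 1.52 (adjusted p = 0.013). Trim54, a muscle ring finger protein, was lower by a ratio of counts of 3230 (counting interval 579 to 128000). The 15 muscle genes sum to 33800 ± 19300 CPM on control diet, 30800 ± 50400 with NaKtide, 145 on Western diet and 1440 on Western diet with NaKtide. Of the 518 genes called lower, 237 are muscle-rich, that is 2-fold or more above the Western diet mean in the muscle-laden control-diet NaKtide library 2, and 281 are not.

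Cholesterol synthesis rose in subcutaneous fat with 17 of 21 genes called (20 over the list alone, camera adjusted p = 7.66e-19, 0.301 with an estimated correlation). In these libraries the mitochondrial mRNA share was 2.91% against 7.29% (exact p = 0.00794, adjusted p = 0.0361) and fibroblast progenitor markers summed to 1240 against 713 CPM (exact p = 0.0159, adjusted p = 0.0497). Fatty acid synthesis rose with 4 of 21 (7 higher and 1 lower over the list alone, adjusted p = 0.00119, 0.698 with an estimated correlation). The clock group had 1 higher and 6 lower of 17 (2 and 9 over the list alone, adjusted p = 0.0214, 0.523 with an estimated correlation). All 15 muscle genes were called lower (15 over the list alone, adjusted p = 1.82e-19, 0.301 with an estimated correlation). Of 15226 genes 854 were called, 336 higher and 518 lower, against 3599 at unadjusted p under 0.05. The count ran from 200 (without Western diet replicate 3) to 1413 (without control replicate 4), past 1.5 times for 8 of the 10 libraries. DESeq2 called 1727, voom with quality weights 3717, the 2 groups alone 2104 and a test with no low-count filter 561.

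With NaKtide on Western diet the same lipid genes lay lower in subcutaneous fat, but none passed correction. Lss had a log2 change of -1.55 ± 0.35 (adjusted p = 0.14, 40.9 ± 18.9 against 120 ± 37.6 CPM). The squalene epoxidase Sqle had -1.76 ± 0.40 (adjusted p = 0.14) and Acly -1.97 ± 0.49 (adjusted p = 0.17, 178 ± 73.0 against 697 ± 377 CPM). The adipokines Lep (0.00 ± 0.46, adjusted p = 1, 2310 ± 553 against 2300 ± 274 CPM) and Adipoq (0.35 ± 0.24, adjusted p = 0.62) were not called, and neither was the kinase Src (0.79 ± 0.31, adjusted p = 0.3). As groups, cholesterol synthesis lay lower with 0 of 21 called (18 over the list alone, camera adjusted p = 1.2e-19, 0.143 with an estimated correlation). Fatty acid synthesis lay lower with 0 of 21 (8 over the list alone, adjusted p = 1.15e-10, 0.143 with an estimated correlation). The muscle genes lay higher with 0 of 15 called (12 over the list alone, adjusted p = 0.000411, 0.94 with an estimated correlation). Other cell markers differed in sum, testis 86.5 against 0.213 CPM (exact p = 0.00794, adjusted p = 0.0994) and mesothelium 29.8 against 1.74 (exact p = 0.0238, adjusted p = 0.108). Adipocyte markers were 19600 against 17200 CPM (exact p = 0.0317, adjusted p = 0.122) and fibroblast progenitor markers 926 against 1240 (exact p = 0.0159, adjusted p = 0.0994). NaKtide libraries 1 and 4 hold 315 and 101 CPM of testis genes. edgeR called 0 genes, with a smallest adjusted p of 0.086 and 1873 genes at unadjusted p under 0.05. DESeq2 called 194, voom with quality weights 638 and a fit of the 2 groups alone 158. Of simulated 2-fold changes put into this comparison edgeR recovered 62%, and of 4-fold changes 90%.

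On control diet NaKtide gave 0 calls in subcutaneous fat, with a smallest adjusted p of 0.792, 918 genes at unadjusted p under 0.05, and 0 calls by DESeq2 and by voom with quality weights. The endothelial receptor Tie1 had a log2 change of -0.73 ± 0.28 and the junction protein Esam -0.55 ± 0.22 (adjusted p = 0.79 each). The endothelial group lay lower (7 of 11 over the list alone, camera adjusted p = 7.8e-09, 0.714 with an estimated correlation). Lep (0.45 ± 0.46, adjusted p = 0.87) was not called. The muscle group has a median log2 change of 0.699 and a mean of 0.647, yet camera, which runs on log2 CPM, places it lower (adjusted p = 0.000791, 0.718 with an estimated correlation). Library 2 of the NaKtide group holds 120000 CPM of muscle genes and the other group 33800 ± 19300.

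The interaction in subcutaneous fat called 0 genes, with a smallest adjusted p of 0.214 and 1712 genes at unadjusted p under 0.05. DESeq2 called 56. The sterol genes Hsd17b7 (-2.45 ± 0.56) and Sqle (-2.39 ± 0.57) led the lower side with adjusted p = 0.26 each. Cholesterol synthesis lay lower with 12 of 21 over the list alone (camera adjusted p = 1.13e-12, 0.526 with an estimated correlation). Leaving out control-diet NaKtide replicate 2, the muscle-laden library, gave 35 calls. Since edgeR called 0 genes for NaKtide on Western diet here, it gave 0 of the 854 diet genes as moved back, where DESeq2 gave 105 and voom with quality weights 370. Over all genes r was -0.668 (covariance -0.414), where simulations gave -0.487 (covariance -0.0675). Split Western diet libraries gave -0.572 (-0.648 to -0.463, covariance -0.401), with 0 opposite genes in both.

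**Figure D3:**
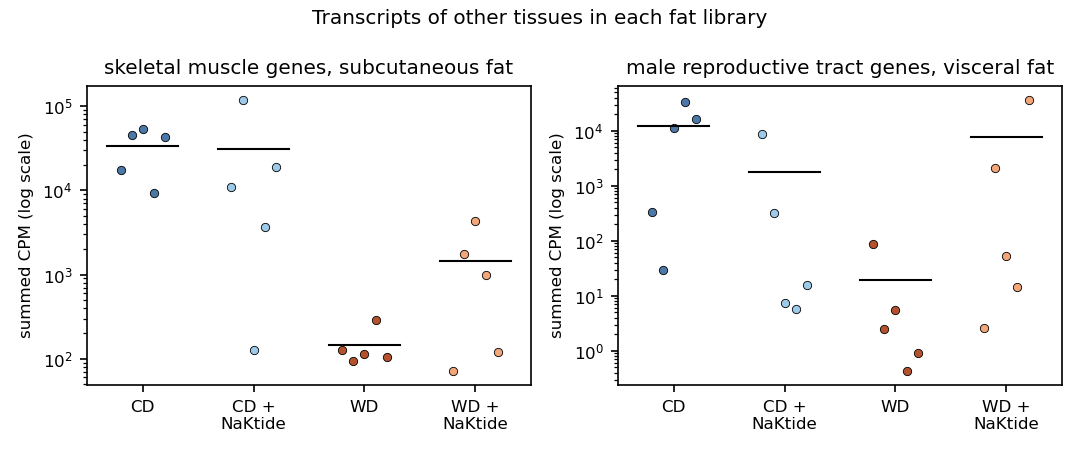
Summed CPM on a log scale of the skeletal muscle genes in subcutaneous fat and of the male reproductive tract genes in visceral fat, with 1 point per library and a line at the mean of each group of 5. Muscle genes are high in the control-diet libraries (33800 ± 19300 CPM), and tract genes reach 36900 CPM in library 5 of the visceral Western diet group with NaKtide.

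In visceral fat, the libraries labelled Western diet carry the signature of inflamed, remodelling fat. Trem2, the receptor of lipid-associated macrophages (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), rose by 3.61 ± 0.45 (adjusted p = 0.00013, 92.5 ± 48.4 against 7.54 ± 3.55 CPM). The Fc receptor Fcgr1 rose by 2.97 ± 0.36 (adjusted p = 0.00012). The macrophage elastase Mmp12 rose by 5.22 ± 0.83 (adjusted p = 0.00056). The monocyte attractant Ccl2 rose by 5.61 ± 0.77 (adjusted p = 0.00023, 102 ± 35.3 against 2.07 ± 1.46 CPM) and the acute-phase protein Saa3 by 4.14 ± 0.51 (adjusted p = 0.00012). Col6a1, a collagen that stiffens obese fat, rose by 2.69 ± 0.52 (adjusted p = 0.0024, 678 ± 207 against 105 ± 61.4 CPM). The matrix protein Fn1 rose by 3.22 ± 0.64 (adjusted p = 0.0029). Scd2 and the sterol sensor Insig1 rose by 2.50 ± 0.34 (adjusted p = 0.00022) and 2.59 ± 0.38 (adjusted p = 0.00031). The clock output factor Hlf fell by 2.58 ± 0.38 (adjusted p = 0.00036).

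The largest falls in visceral fat are genes of the epididymis. Lcn8, a lipocalin of the epididymal head, went from 1870 ± 3210 to 0.204 ± 0.334 CPM (log2 -13.06 ± 4.07, adjusted p = 0.031). The sperm coat protein Crisp1 fell by 10.79 ± 3.32 (adjusted p = 0.03). The defensin Defb47, with 0 counts on Western diet, was at least 4090-fold lower with counting error. The group of male tract genes had 8 of 9 lower (9 over the list alone, camera adjusted p = 0.00121, 0.569 with an estimated correlation). Without the 8 visceral libraries above 1000 CPM of tract and testis genes, a setting chosen after seeing the data, Crisp1 had a log2 change of -4.27 that missed the threshold (adjusted p = 0.0507). That setting leaves 2 control libraries, which still hold 328 and 29.7 CPM of tract genes.

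Macrophage genes in visceral fat had 18 higher and 1 lower of 22 (18 and 1 over the list alone, camera adjusted p = 7.07e-16, 0.154 with an estimated correlation). Inflammatory mediators had 15 and 1 of 21 (15 and 2 over the list alone, adjusted p = 5.52e-10, 0.0528 with an estimated correlation). Their sum ran the other way, 689 against 1440 CPM (exact p = 0.444, adjusted p = 0.637), with Lcn2 at 26.4 ± 6.63 against 1450 ± 2090 CPM. Matrix genes rose with 19 of 24 (22 over the list alone, adjusted p = 2.34e-12, 0.252 with an estimated correlation). Summed markers of fibroblast progenitors were 1380 against 498 CPM and of mast cells 56.1 against 22.2 (exact p = 0.00794, adjusted p = 0.0496 each). Lymphocyte genes rose with 6 of 13 (7 over the list alone, adjusted p = 2.8e-05, 0.195 with an estimated correlation). Of 17235 genes 4287 were called, 1816 higher and 2471 lower, against 7174 at unadjusted p under 0.05. The median log2 change of all genes was -0.217 (0.000243 without the tract-rich libraries), and -0.268 with RLE scaling, which called 4428. Spread between the visceral libraries is wide (biological coefficient of variation 0.675 against 0.251 in liver). The count ran from 1570 (without Western diet replicate 3) to 5091 (without control replicate 2). It was 1874, 2078, 1756 and 1781 without control replicates 3 and 4 and Western diet replicates 4 and 5. A test with no low-count filter called 1936 and the 2 groups alone 2114.

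The visceral libraries labelled NaKtide on Western diet lack that inflammatory signature. Itgax, the CD11c integrin of adipose macrophages, fell by 4.36 ± 0.58 (adjusted p = 0.00034, 3.95 ± 2.76 against 82.9 ± 65.8 CPM). Mpeg1, a pore-forming protein of macrophages, fell by 2.36 ± 0.33 (adjusted p = 0.00042). Saa3 fell by 3.49 ± 0.49 (adjusted p = 0.00042), and the cytokine feedback inhibitor Socs3 fell by 2.96 ± 0.43 (adjusted p = 0.00052). The smooth muscle actin Acta2 fell by 1.25 ± 0.27 (adjusted p = 0.0068). Respiratory chain subunits rose, Ndufa9 of complex I by 0.73 ± 0.15 (adjusted p = 0.0056) and Uqcrfs1 of complex III by 1.04 ± 0.23 (adjusted p = 0.0081). The adipokine Cfd (adipsin), which obesity lowers, rose by 2.23 ± 0.52 (adjusted p = 0.01, 7200 ± 2950 against 1530 ± 652 CPM). Lep (-1.93 ± 0.76, adjusted p = 0.087, 868 ± 840 against 3320 ± 264 CPM), Adipoq (0.82 ± 0.57, adjusted p = 0.33) and Src (-0.08 ± 0.19, adjusted p = 0.82) were not called.

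By gene group, macrophage genes fell in visceral fat with 18 of 22 (18 over the list alone, camera adjusted p = 4.59e-14, 0.112 with an estimated correlation). Inflammatory mediators fell with 13 of 21 (13 lower and 1 higher over the list alone, adjusted p = 8.48e-10, 0.053 with an estimated correlation), while their sum was 1210 against 689 CPM (exact p = 1). That sum was 5074 CPM in NaKtide library 5, which carries tract transcripts, and 174 to 323 CPM in the other NaKtide libraries. The Western diet libraries have 581 to 766 CPM. Fibroblast progenitor markers summed to 695 against 1380 CPM (exact p = 0.00794, adjusted p = 0.0305). Nuclear genes of oxidative phosphorylation rose with 13 of 23 (19 over the list alone, adjusted p = 1.47e-09, 0.593 with an estimated correlation). In the same libraries the mitochondrial mRNA share was 3.71% against 2.07% (exact p = 0.00794, adjusted p = 0.0305) and adipocyte markers summed to 20600 against 13800 CPM (exact p = 0.0476, adjusted p = 0.108). Male tract genes rose beside them with 4 of 9 called (9 over the list alone, adjusted p = 0.0982), Lcn8 by 13.11 ± 4.08 (adjusted p = 0.042). Of 17235 genes 2270 were called, 1073 higher and 1197 lower, against 5732 at unadjusted p under 0.05. RLE scaling turned this to 1194 higher and 1152 lower. The count ran from 1031 (without Western diet replicate 3) to 3770 (without Western diet replicate 2). It was 1396, 1125 and 1169 without Western diet replicates 1, 4 and 5 and 1278 and 1327 without NaKtide replicates 2 and 4. DESeq2 called 4602, voom with quality weights 7392, a test with no low-count filter 985 and the fit without the tract-rich libraries 3555.

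The visceral libraries labelled NaKtide on control diet show the opposite, a gain of the genes that mark Western diet. This contrast and the diet contrast use the same control libraries, so errors push their log2 changes the same way. How much of the likeness this gives was not tested. Trem2 rose by 4.2 ± 0.46 (adjusted p = 8.9e-05, 139 ± 37.7 against 7.54 ± 3.55 CPM) and Mpeg1 by 2.71 ± 0.33 (adjusted p = 0.00025). Saa3 rose by 5.40 ± 0.54 (adjusted p = 2.9e-05, 187 ± 44.2 against 4.4 ± 0.474 CPM). Il1rn, which blocks interleukin 1, rose by 5.24 ± 0.82 (adjusted p = 0.00098). The collagens Col6a1 and Col1a1 rose by 3.08 ± 0.53 (adjusted p = 0.0017) and 2.65 ± 0.53 (adjusted p = 0.0048, 632 ± 160 against 101 ± 60.8 CPM). Acsm3, a medium-chain acyl-CoA synthetase, fell by 4.68 ± 0.94 (adjusted p = 0.0048). Cfd fell by 1.92 ± 0.51 (adjusted p = 0.028), a call that a test with no low-count filter ended (adjusted p = 0.096). Lep (1.89 ± 0.75, adjusted p = 0.13), Adipoq (0.23, adjusted p = 0.79) and Src (-0.31, adjusted p = 0.28) were not called. Tnf and Il6 fell under the count filter in fat, where Tnf averaged 0.455, 1.6, 1.04 and 0.421 CPM in visceral control, control with NaKtide, Western and Western with NaKtide libraries.

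Macrophage genes rose in visceral fat on control diet with 18 of 22 (18 higher and 1 lower over the list alone, camera adjusted p = 1.62e-20, 0.0635 with an estimated correlation). Inflammatory mediators rose with 10 of 21 (12 over the list alone, adjusted p = 1.16e-09, 0.0606 with an estimated correlation), while their sum was 714 against 1440 CPM (exact p = 0.46, adjusted p = 0.672). The control mean rests on tract-rich libraries 4 and 5, with 4229 and 2041 CPM, beside 240 to 435 CPM in the other control libraries. Matrix genes rose with 9 of 24 (18 over the list alone, adjusted p = 4e-14, 0.292 with an estimated correlation). Fibroblast progenitor markers summed to 1230 against 498 CPM (exact p = 0.00794, adjusted p = 0.0567). Of 17235 genes 1233 were called, 906 higher and 327 lower, against 4609 at unadjusted p under 0.05. The median log2 change of all genes was -0.23 (-0.00359 without the tract-rich libraries), and -0.26 with RLE scaling, which called 1246. The count ran from 628 (without NaKtide replicate 2) to 3115 (without NaKtide replicate 1, which carries tract and testis transcripts). It was 760 and 814 without control replicates 3 and 4 and 711 and 759 without NaKtide replicates 4 and 5. DESeq2 called 2919, voom with quality weights 3571, a test with no low-count filter 655, the 2 groups alone 712 and the fit without tract-rich libraries 2288.

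**Figure D4:**
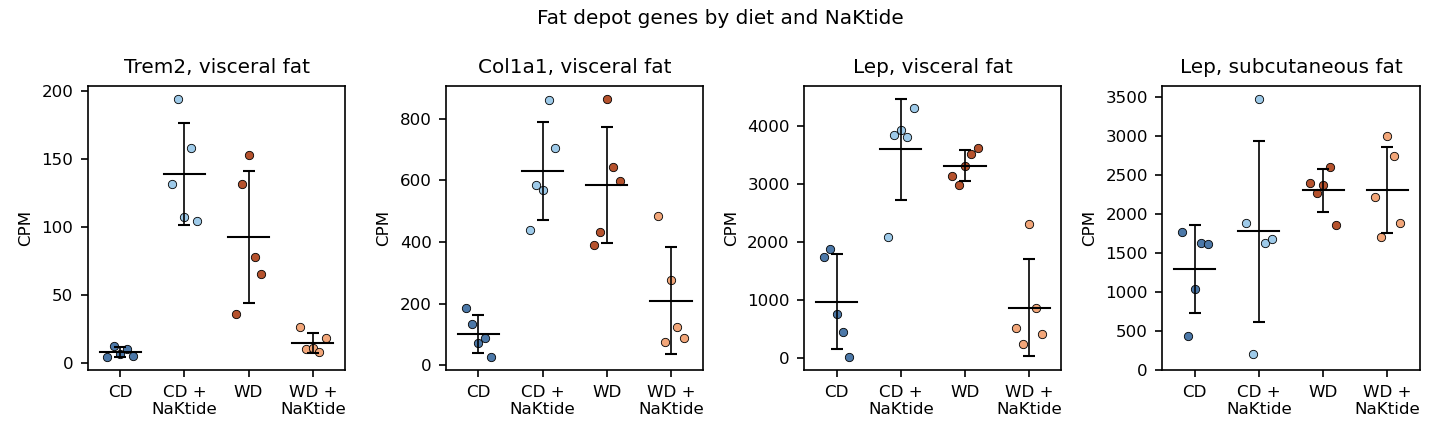
CPM of Trem2, Col1a1 and Lep in visceral fat and of Lep in subcutaneous fat, with 1 point per library, 4 groups of 5, and lines at the mean ± SD. In visceral fat the control-diet NaKtide libraries resemble the Western diet libraries (Trem2 139 ± 37.7 and 92.5 ± 48.4 CPM), while Lep in subcutaneous fat is alike with and without NaKtide on Western diet (2310 ± 553 and 2300 ± 274 CPM).

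Under the labels as given, the NaKtide effect in visceral fat differed between diets. The effect on Western diet minus that on control diet was -6.87 ± 0.62 for Trem2 (adjusted p = 2.3e-06) and -8.89 ± 0.72 for Saa3 (adjusted p = 1e-06). It was -4.76 ± 0.72 for Col6a1 (adjusted p = 0.00016) and -3.82 ± 1.07 for the satiety hormone Lep (adjusted p = 0.014). For Cfd it was 4.16 ± 0.73 (adjusted p = 0.00057) and for the mitochondrial oxidase subunit mt-Co3 2.75 ± 0.61 (adjusted p = 0.0033). Macrophage genes had 1 higher and 18 lower of 22 (1 and 18 over the list alone, camera adjusted p = 4.34e-17, 0.103 with an estimated correlation). Matrix genes had 21 lower of 24 (23 over the list alone, adjusted p = 5.93e-12, 0.326 with an estimated correlation). Mitochondrially encoded genes had 11 higher of 13 (12 over the list alone, adjusted p = 0.00143, 0.694 with an estimated correlation). Of 17235 genes 5549 differed, 3241 higher and 2308 lower, against 7538 at unadjusted p under 0.05. The median over all genes was 0.302 (0.0261 without the tract-rich libraries), and 0.367 with RLE scaling, which called 5686. No omission of a single library moved this count by more than 1.5 times (3860 to 6454).

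Of the genes Western diet changed in visceral fat, 1707 moved the opposite way in the libraries labelled NaKtide on Western diet (946 higher and then lower, 761 lower and then higher, with 126 and 154 for independent lists) and 0 the same way (113 and 172). Tract and testis RNA ran alongside, with 3 control, 1 Western diet and 3 Western diet NaKtide libraries above the limit. The epididymal gene Lcn8, called in both contrasts, is among the 761. Over all genes r was -0.848 (covariance -2.15), against a simulated median of -0.502 (covariance -0.373, 0 opposite genes) from the shared Western diet libraries alone. Simulated genes varied independently of each other, whereas other splits of the same libraries into groups gave up to 845 opposite genes. With these libraries split between the contrasts r was -0.667 (-0.848 to -0.422, covariance -2.24) and the opposite count 413 (171 to 526). Leaving out Western diet replicate 3 gave 721 and replicate 2 gave 2963. DESeq2 gave 3593, voom with quality weights 4925 and a test with no low-count filter 732.

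**Figure D5:**
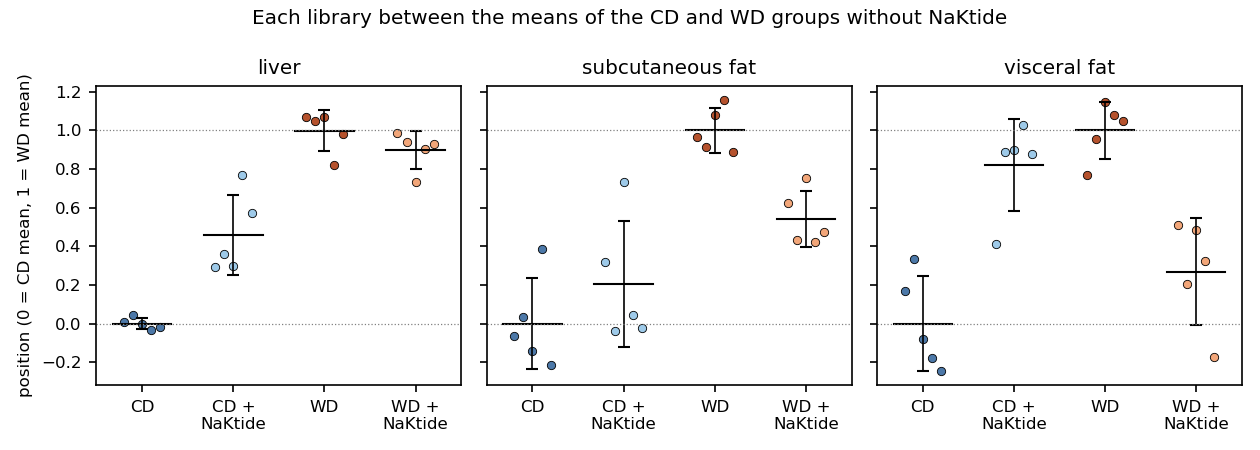
Position of each library between the control-diet mean (0) and the Western diet mean (1) over genes called for diet in its tissue, with points for libraries and lines at the mean ± SD of 5. NaKtide on control diet lies at 0.459 ± 0.208 in liver, 0.206 ± 0.327 in subcutaneous fat and 0.821 ± 0.237 in visceral fat, and NaKtide on Western diet at 0.899 ± 0.098, 0.542 ± 0.145 and 0.269 ± 0.278. Genes number 1097 in liver, 617 in subcutaneous fat, where muscle-rich genes are left out, and 2871 in visceral fat, where they were called without the tract-rich libraries. The genes were picked in the same control and Western diet libraries that set 0 and 1. The NaKtide groups, not used in that choice, would therefore tend to lie between the ends without any NaKtide effect.

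Transcription factors of depot development differed between the depots on control diet. Shox2 and Tbx15, homeobox and T-box factors of subcutaneous preadipocytes, were lower in visceral fat, with log2 changes of -4.61 ± 0.92 (adjusted p = 0.0025) and -5.88 ± 1.24 (adjusted p = 0.0032). Tcf21, a visceral progenitor factor, was higher by a ratio of counts of 146 (counting interval 25.9 to 5810) and the mesothelial uroplakin Upk3b by 207 (56.9 to 1710). Without the tract-rich libraries neither Shox2 (adjusted p = 0.149) nor Tbx15 (adjusted p = 0.152) was called, and voom with quality weights gave adjusted p = 0.4 and 0.0598. The summed subcutaneous depot genes were 116 and 76.5 CPM in visceral control libraries 1 and 2, inside the range of the subcutaneous control libraries (73.1 to 182), and 27.4, 16.1 and 3.55 in tract-rich libraries 3 to 5. Visceral depot genes were 41.2 and 68.4 CPM in visceral control libraries 1 and 2 against 7.68 to 14.9 in the subcutaneous control libraries, and mesothelial genes 45.1 and 85.1 against 1.88 to 4.36. Of the 89 named genes called here, 0 kept the call under every setting. Hadhb of mitochondrial fat oxidation was lower at -1.27 ± 0.24 (adjusted p = 0.0016). Other tissue separates the depots too. Adam7 of the epididymis was higher by 12.59 ± 2.91 (adjusted p = 0.005) and Atp2a1, the calcium pump of fast muscle, lower at -12.44 ± 2.65 (adjusted p = 0.0034).

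All 15 muscle genes were lower in visceral fat (15 over the list alone, camera adjusted p = 9.18e-23, 0.109 with an estimated correlation). All 9 male tract genes were higher (9 over the list alone, adjusted p = 1.09e-06, 0.184 with an estimated correlation), and 7 of 9 mesothelial genes were higher (7 over the list alone, adjusted p = 2.48e-05, 0.184 with an estimated correlation). Of 17788 genes 4842 were called, 3539 higher and 1303 lower, against 6966 at unadjusted p under 0.05. The median over all genes was 0.133 (0.0034 without the tract-rich libraries), and 0.2 with RLE scaling, which called 5127. The count was 1740 without visceral control replicate 5, 3 without the tract-rich libraries, which leaves 2 visceral control libraries, and 381 with voom quality weights.

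Diet moved macrophage genes differently in the depots. The diet effect in visceral fat minus that in subcutaneous fat was 3.2 ± 0.64 for the scavenger receptor Msr1 (adjusted p = 0.012), 3.12 ± 0.68 for Fcgr1 (adjusted p = 0.017) and 3.30 ± 0.62 for Socs3 (adjusted p = 0.0076). The macrophage group had 13 higher of 22 (19 higher and 1 lower over the list alone, camera adjusted p = 1.35e-14, 0.186 with an estimated correlation). Pvalb, the calcium buffer of fast muscle, led the muscle genes at 12.25 ± 2.13 (adjusted p = 0.0065). Of these 15 of 15 were higher (15 over the list alone, adjusted p = 2.07e-23, 0.126 with an estimated correlation), and subcutaneous control libraries hold 33800 ± 19300 CPM of them. Of 17788 genes 396 differed, 277 higher and 119 lower, against 3685 at unadjusted p under 0.05. The median over all genes was -0.192 (0.0187 without the tract-rich libraries), and -0.21 with RLE scaling, which called 417. The count ran from 132 (without visceral Western diet replicate 3) to 1169 (without visceral control replicate 1). It was 1 without the tract-rich libraries, where Msr1 had adjusted p = 0.14, 1377 with DESeq2 and 204 with no low-count filter.

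The NaKtide effect on Western diet also differed between depots for immune genes. Visceral minus subcutaneous, it was -2.93 ± 0.60 for Mpeg1 (adjusted p = 0.0092) and -5.12 ± 1.07 for Itgax (adjusted p = 0.011). It was -4.61 ± 0.99 for the neutrophil chemokine Cxcl1 (adjusted p = 0.013) and -2.82 ± 0.61 for Socs3 (adjusted p = 0.013). Macrophage genes had 11 lower of 22 (17 lower and 1 higher over the list alone, camera adjusted p = 9.46e-15, 0.185 with an estimated correlation). Mesothelial genes moved beside them with 3 lower of 9 (7 over the list alone, adjusted p = 3.23e-05, 0.351 with an estimated correlation), among them Gpm6a at -6.05 ± 1.46 (adjusted p = 0.023). Their sum is 97 and 45.5 CPM in subcutaneous NaKtide libraries 1 and 4 and 3.85 CPM in visceral NaKtide library 1, each on the other depot's side of 10 CPM. Subcutaneous and visceral library 1 also had 33.1 and 85.2 CPM of subcutaneous depot genes, 70 and 18 CPM of visceral depot genes, and 159 and 25.8 CPM of Trem2. Whether these 2 libraries are exchanged was not tested, and an exchange would change the values for NaKtide on Western diet in both depots. The count was 185 without the subcutaneous library and 504 without the visceral one. Of 17788 genes 519 differed, 179 higher and 340 lower, against 3784 at unadjusted p under 0.05, and DESeq2 called 1572. Without those 3 libraries, a setting chosen after seeing the data, 37 genes differed and Mpeg1 had adjusted p = 0.059. Single omissions ran from 172 (visceral NaKtide replicate 4) to 1591 (visceral Western diet replicate 2).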

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

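The depot test of the NaKtide effect as an explanation, the test of dilution on the adipocyte markers, the fits without tract-rich visceral libraries and the mitochondrial covariate are tests chosen only after the results were seen; the other tests below were written before their own results, but muscle-rich genes were defined only after the muscle in subcutaneous control-diet NaKtide library 2 was seen.

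Single libraries far from the 4 others of their group were picked out 21 times in 64 groups checked, by the gap to the nearest library over the range of the group. Chance picks out about 1 in 20 groups only if values are independent and normally distributed. The checks reuse the same libraries and include skewed sums, so 21 of 64 cannot be weighed against that rate. Subcutaneous control-diet NaKtide library 2 stands apart most often, with 3.49 M counts (nearest 5.87), 17800 genes detected (nearest 19900), a mitochondrial mRNA share of 17.5% (nearest 6.26%), 120000 CPM of muscle genes (nearest 18900) and a median rank correlation with its group of 0.75 (nearest 0.891). In visceral fat, control-diet library 5 has 28100 genes detected (nearest 23400), 7900 CPM of testis genes (nearest 1140) and a rank correlation of 0.444 (nearest 0.683). Control-diet NaKtide library 1 has 26600 genes (nearest 21700), 8700 CPM of male tract genes (nearest 321), 2650 CPM of testis genes (nearest 5.63) and a rank correlation of 0.76 (nearest 0.966). Western diet library 1 has 25700 genes (nearest 22200), 87.8 CPM of tract genes (nearest 5.49) and 1130 CPM of testis genes (nearest 5.81). Western diet library 5 with NaKtide has 36900 CPM of tract genes (nearest 2120) and a rank correlation of 0.681 (nearest 0.904).

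Smaller departures are muscle genes at 12.2 CPM in liver Western diet library 1 (nearest 8.84) and at 285 CPM in subcutaneous Western diet library 4 (nearest 127). The rank correlation with the group is 0.895 in liver control-diet library 3 (nearest 0.936) and 0.904 in liver Western diet library 1 with NaKtide (nearest 0.958).

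Tested differences between groups in the effect of the same factor also stand out. The NaKtide effect differed between diets for 649 genes in liver and 5549 in visceral fat. Between fat depots the diet effect differed for 396 genes and the NaKtide effect on Western diet for 519.

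The same libraries were also split into other groups of the same size, 100 ways in each tissue and 60 in fat. In some contrasts only the real split, 1 of 100, reached the count. That holds for diet in liver (1097, highest other 376), NaKtide on control diet in liver (201, highest other 9), the liver interaction (649, highest other 3), diet in subcutaneous fat (854, highest other 0), and in visceral fat for diet (4287, highest other 3932), NaKtide on Western diet (2270, highest other 1946), the interaction (5549, highest other 4433) and the genes moved back (1707, highest other 845). In fat, 1 of 60 splits reached the count for the depots on control diet (4842, highest other 4541) and for the depot difference in the NaKtide effect (519, highest other 279). For interactions, depot differences and genes moved back, the shuffled groups carry no effect of diet or NaKtide at all. These splits therefore cannot exclude chance for the interaction, the depot difference or the reversal alone. Other tissue that differs between the same groups, such as tract RNA in visceral fat, would also set the real split apart.

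Elsewhere other splits reached the count. For NaKtide on Western diet in liver 4 of 100 did (622, highest other 3904, with Western diet replicate 1 and NaKtide replicate 1 exchanged), for the liver genes moved back 3 of 100 (113, highest other 508), for NaKtide on control diet in visceral fat 5 of 100 (1233, highest other 4648) and for the depot difference in the diet effect 2 of 60 (396, highest other 2469). A split with several times the real count points to structure among the samples other than the groups, and for NaKtide on control diet in visceral fat chance is not excluded. In subcutaneous fat the splits decide nothing where the real count is 0, since every split reaches 0. That is so for NaKtide on Western diet (highest other 0), NaKtide on control diet (highest other 2531), the interaction (highest other 934) and the genes moved back (highest other 0).

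In visceral fat the diet effect runs opposite ways with and without NaKtide. Among the 4287 genes called for diet, r between the diet effect with NaKtide and without it is -0.784, and 238 genes (5.55%) share the sign. Leaving out single libraries moved this r between -0.927 and -0.0506, the latter without Western diet library 5 with NaKtide, which holds 36900 CPM of tract genes, and r over all genes between -0.83 and 0.0769. So 1 library can nearly remove the correlation. Without all 8 tract-rich libraries, that library among them, r was -0.463 over all genes and -0.717 over genes called for diet. Under the labels as given this argues against epididymis and testis RNA as the whole cause. The fit leaves 2 libraries in 2 of the groups. With NaKtide on Western diet these are libraries 1 and 4, and visceral library 1 holds only 3.85 CPM of mesothelial genes. Whether that library is subcutaneous fat was not tested, so the argument is limited. Exchanged labels of the visceral NaKtide groups remain a candidate explanation: over genes called for diet r is 0.668 in subcutaneous fat, with muscle-rich genes left out, and 0.599 in liver. Over all genes r is 0.747 and 0.293 there (0.431 to 0.768 and 0.114 to 0.407 without 1 library) and -0.518 in visceral fat. The 0.747 includes muscle-rich genes, and muscle RNA in both subcutaneous control-diet groups can give a positive r without a diet effect on fat. The 0.668 still rests partly on 281 lower genes for which muscle cannot be told apart from diet. In subcutaneous fat 0 genes were called for diet within the NaKtide groups. A diet-dependent NaKtide effect of visceral fat alone stays open beside it, as 519 genes differ between depots in the NaKtide effect, and the design gives no value that tells it from wrong labels.

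In subcutaneous fat many genes fall on Western diet. Of the 518 lower genes 45.8% are muscle-rich against 5.71% of all genes tested, which decides little, since muscle-rich is measured against the same Western diet mean and a gene that diet lowers can meet it. Muscle tissue in the control-diet libraries likely accounts for the muscle-rich part, as 222 of these genes, none on the muscle list, follow the muscle genes over the 5 control-diet libraries with a median rank correlation of 0.9. For the other 281 lower genes the median is 0.3, between the bounds set for either answer, so muscle cannot be told apart from a diet effect there. For the genes called higher, dilution of fat RNA by muscle RNA as the whole cause would raise all fat transcripts alike. The 10 adipocyte markers did not rise as a set, with a median of -0.179 (SD 0.672, highest 0.827) and 0 called. The genes called higher have a median of 1.01, a gap of 1.19. Neither value sets the rise that dilution would give, since these genes were selected for a rise. A small rise would lie within the spread of the markers, so dilution is not excluded. A part played by dilution and a diet effect both stay open.

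In liver NaKtide on Western diet lowers male-biased genes and raises macrophage genes. RNA quality was taken as the mitochondrial mRNA share. As the whole cause it is argued against for the macrophage genes, whose median went from 1.08 to 1.01 with the share as a covariate. For the male-biased genes the median went from -1.35 to -0.892, a larger loss, so RNA quality stays open there. Of the mean size of the list medians 0.779 remained, a value that joins both lists and cannot decide for either alone. Called members went from 8 to 4 of 13 male-biased genes and from 9 to 4 of 20 macrophage genes. Why those calls ended was not tested. Transcript length cannot be told apart from the NaKtide effect at a rank correlation of -0.127, which is small but past the bound set for excluding it. An effect of the treatment, doxycycline included, stays open as a hypothesis. In other contrasts the rank correlation of log2 change with transcript length was larger in size. It reached 0.314 for NaKtide on control diet in liver and -0.372 for NaKtide on Western diet in visceral fat. For diet in visceral fat it was 0.287. What part transcript length plays in the changes of those contrasts was not tested.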

How the results depend on the processing

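The fits without tract-rich visceral libraries, without muscle-rich genes, without muscle-containing livers, with the mitochondrial covariate and by mesothelial level were chosen only after the data were seen; all other settings were fixed before. The cause was not tested unless a sentence gives it. Counts are genes called, with changes of more than 1.5 times printed.

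RLE scaling left every count within 1.5 times. No low-count filter, which tests more genes, gave 308 for NaKtide on control diet in liver, 561 for diet in subcutaneous fat, and in visceral fat 1936 for diet, 985 and 655 for NaKtide on Western and control diet and 732 for genes moved back, with 204 and 211 for the depot differences in the diet and NaKtide effects.

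DESeq2 gave 1068 and 433 for NaKtide on Western and control diet in liver, 1559 for the interaction and 182 for genes moved back. In subcutaneous fat it gave 1727 for diet, 194 for NaKtide on Western diet, 56 for the interaction and 105 for genes moved back, in visceral fat 4602 and 2919 for NaKtide on Western and control diet and 3593 for genes moved back, and 1377 and 1572 for the depot differences. On simulated data its share of false calls was above edgeR's in each comparison run with changed genes.

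Voom with quality weights gave 1744 for diet in liver, 3904 for NaKtide on Western diet, 3243 for the interaction and 493 for genes moved back. It gave 3717 for diet, 638 for NaKtide on Western diet and 370 for genes moved back in subcutaneous fat, and 6507, 7392, 3571 and 4925 for diet, NaKtide on Western diet, NaKtide on control diet and genes moved back in visceral fat. Between depots it gave 381 on control diet, 653 for the diet effect and 4224 for the NaKtide effect.

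Fitting the 2 groups alone gave 693, 321 and 124 in liver for diet, NaKtide on Western diet and NaKtide on control diet, 2104 and 158 in subcutaneous fat for diet and NaKtide on Western diet, and 2114 and 712 in visceral fat for diet and NaKtide on control diet.

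With a replicate block, which costs degrees of freedom, liver gave 360 and 62 for NaKtide on Western and control diet, 155 for the interaction and 62 for genes moved back, visceral fat 2671 for diet and 1122 for genes moved back, and the depot difference in the NaKtide effect 345. Replicate numbers show no sign of pairing: residuals of equal numbers correlate at a mean r of -0.0829 in liver, -0.0125 in subcutaneous fat, -0.0496 in visceral fat and -0.0573 between depots.

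The mitochondrial covariate gave 152 for NaKtide on Western diet, 438 on control diet, 168 for the interaction and 48 for genes moved back in liver. Without the muscle-containing livers, which leaves 3 control libraries, diet gave 656, NaKtide on control diet 83, the interaction 364 and genes moved back 73. Without the tract-rich visceral libraries, which leaves as few as 2 per group, NaKtide gave 3555 on Western and 2288 on control diet, and the depot contrasts 3 on control diet, 1 for the diet effect and 1088 for the NaKtide effect. Without muscle-rich genes the depot difference in the diet effect gave 240. Without the libraries on the other depot's side of the mesothelium level, its NaKtide counterpart gave 37.

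Leaving out each library in turn gave in liver 773 to 1134 for diet, 224 to 2281 for NaKtide on Western diet, 59 to 402 on control diet, 192 to 2738 for the interaction and 44 to 251 for genes moved back. Subcutaneous fat gave 200 to 1413 for diet, 0 to 35 for the interaction and 0 throughout for NaKtide on either diet. Visceral fat gave 1570 to 5091 for diet, 1031 to 3770 and 628 to 3115 for NaKtide on Western and control diet, 3860 to 6454 for the interaction and 721 to 2963 for genes moved back. Depots gave 1740 to 6694 on control diet, 132 to 1169 for the diet effect and 172 to 1591 for the NaKtide effect.

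Of the 201 list calls by camera, 0 remained with an estimated correlation, and fry made 117. Among 1329 named genes and contrasts 644 were called, of which 273 kept the call under every setting and 297 under all but the omission of single libraries. Their 26846 values under other settings include 23972 that stayed, 2036 weaker, 624 stronger and 17 of reversed sign.

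The reversed values given here are log2 changes. Voom with quality weights gave Cd52 0.112 for diet and -0.00625 for the interaction in visceral fat, and Lcn2 -1.22 for that interaction. Without tract-rich libraries diet gave Cd52 1.28 and Hspa1a 0.0993, and the interaction Cd52 -2.79, Lcn2 -2.77, Atp1b1 -1.07 and Hspa1b -0.195. The same setting gave between depots Ccnb1 -0.103, Ccnb2 -0.308, Cd52 -0.147, Egr2 -0.242, Inha -0.11, Shmt2 -0.114 and Sqle -0.04.

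Depth and spread limit what a 0 can mean. On simulated changes edgeR recovered 24% of 2-fold and 77% of 4-fold interactions in subcutaneous fat and 2% and 34% in visceral fat, and smaller interactions there pass unseen.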

Other observations

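Diet within the NaKtide groups, the muscle-rich genes left out there and the fit without tract-rich libraries are tests chosen after the data were seen; the genes fall under the naming rule, and those shown were selected after their values were seen. Cck, Tph2 and Trdn had the largest rises the naming rule picked in visceral fat with NaKtide on control diet. Cck, the gut peptide hormone (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694, GRCm38), averaged 0.127 ± 0.0783 CPM in the libraries labelled control diet, 94.7 ± 19.2 in control diet with NaKtide and 8.3 ± 1.2 in Western diet. Its log2 change was 9.36 ± 0.49 for NaKtide on control diet (adjusted p = 3.2e-09) and 5.85 ± 0.46 for diet (adjusted p = 1.3e-06), and with NaKtide on Western diet it was lower by a ratio of counts of 141 (counting interval 38.9 to 1170). Tph2, the neuronal enzyme of serotonin synthesis (ENSMUSG00000006764, chromosome 10, 115078641 to 115185022), rose by 8.99 ± 0.58 with NaKtide on control diet (adjusted p = 5.4e-08) and by 7.70 ± 0.56 with diet (adjusted p = 8.1e-07) and fell by 6.50 ± 0.52 with NaKtide on Western diet (adjusted p = 1.7e-06), and in subcutaneous fat averaged 3.7 ± 5.65, 31.2 ± 65.8, 22.2 ± 13.2 and 17.8 ± 10.7 CPM in control, control with NaKtide, Western and Western with NaKtide libraries. Trdn, the calcium-release protein triadin, rose by 6.24 ± 0.84 with diet (adjusted p = 0.00019), and Otop1, a proton channel that obesity induces in fat, by 3.90 ± 0.68 (adjusted p = 0.0011).

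Fxyd5, which modifies Na,K-ATPase activity and cell adhesion, rose with diet in visceral fat by 1.58 ± 0.31 (adjusted p = 0.0025). With NaKtide on control diet it rose by 1.29 ± 0.30 (adjusted p = 0.015). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose with diet by 2.75 ± 0.47 (adjusted p = 0.00093) and the glutathione transferase Gsta4 fell by 2.60 ± 0.44 (adjusted p = 0.00096). Fos, an early gene of cell activation, rose with diet by 3.55 ± 0.53 (adjusted p = 0.00036) and Atf3 by 3.33 ± 0.42 (adjusted p = 0.00014), both also markers of handling time.

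Some clock genes moved in liver with NaKtide on Western diet. Usp2, a deubiquitinase under clock control, rose by 3.63 ± 0.56 (adjusted p = 0.00096, 53.3 ± 17.0 against 4.28 ± 2.25 CPM), and the clock outputs Tef and Dbp by 0.98 ± 0.18 (adjusted p = 0.0045) and 1.02 ± 0.23 (adjusted p = 0.012). Clock fell by 1.34 ± 0.25 (adjusted p = 0.004) and its partner Arntl by 2.66 ± 0.61 (adjusted p = 0.015), from 2.49 ± 1.19 to 0.32 ± 0.344 CPM. As a group 2 rose and 2 fell of 16 (5 and 2 over the list alone, camera adjusted p = 0.261). Their sum was 528 against 371 CPM (exact p = 0.00794, adjusted p = 0.132). With NaKtide on control diet it was 602 against 409 CPM (exact p = 0.00794, adjusted p = 0.0992). The labels give no time of collection, so a different hour of sampling between groups was not tested.

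In the same livers the urinary protein gene Mup7 went from 14200 ± 9310 to 860 ± 982 CPM (log2 -4.04 ± 0.82, adjusted p = 0.007) and Mup9 fell by 5.25 ± 0.90 (adjusted p = 0.0024). The Mup genes are near-identical copies, and how the authors' counting handled such reads is not given. The metallothioneins Mt1 and Mt2, which bind zinc, had interactions of 4.81 ± 1.16 (adjusted p = 0.027) and 5.29 ± 1.46 (adjusted p = 0.042) in liver. Egfr, the receptor of epidermal growth factor, fell by 1.91 ± 0.44 (adjusted p = 0.015).

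Diet effects with and without NaKtide were compared over the genes called for diet. In liver 824 of 1097 (75.1%) kept their sign, and diet within the NaKtide groups called 3189 genes, 1675 higher and 1514 lower. In subcutaneous fat 472 of 617 genes that are not muscle-rich (76.5%) kept their sign and 0 were called within the NaKtide groups. In visceral fat 830 were called within the NaKtide groups, 228 higher and 602 lower, and all 618 called in both had opposite signs. Without the tract-rich libraries 2434 were called, 997 higher and 1437 lower, and of 1390 called in both 1374 had opposite signs and 16 the same.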
